A study of Arabidopsis thaliana with 16 samples.

How the data were processed

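Poly(A) RNA from rosette leaves of 5-week-old Arabidopsis thaliana Col-0 plants was sequenced as 50 bp single-end reads in 16 libraries. Plants had been sprayed at 2 weeks with water or 1 mM jasmonic acid (JA), here called their history, and at 5 weeks with water or 0.1 mM JA, here called the challenge. Leaves were taken 4 h after the challenge, and each library pooled 8 leaves from 2 plants. The 4 groups are named by history and then challenge: W_W, W_JA, JA_W and JA_JA, each with 4 biological replicates per the labels. Control sprays carried matched ethanol, and all sprays held 0.02% Silwet. Plants grew at 21 °C in days of 8.5 h and nights of 15.5 h.

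Each library has 1 deposited table that holds raw read counts per gene and depth-scaled counts (CPM, the count over the sample total times 1e6). The submitters' processing notes list Trimmomatic 0.38, STAR 2.6.1b, HTSeq 0.9.1 and the TAIR10 genome, without their settings or the strandedness of the counting. The deposited CPM were used only to check the counts: dividing the counts by each library's total gave the same values to within 5.09e-11. Totals ran from about 32190200 to 34319900 counted reads (median 34159400), so 1 read is about 0.0293 CPM. The tables list 34262 genes, of which 8507 had no read in any library. Symbols and gene descriptions came from the TAIR10.1 reference annotation, where 32548 identifiers were found. The others were 285 plastid or mitochondrial genes and 1429 noncoding RNA identifiers. No 2 replicates of a group were copies: chi-squared per gene between them ran from 6.38 to 80.7.

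Genes were kept by the edgeR filterByExpr rule by group (minimum count 10, minimum total 15), which left 19224 and removed 15038. Library sizes were scaled with TMM (factors 0.888 to 1.14), and 1 model with a mean for each group was fitted to all 16 libraries (12 residual degrees of freedom; biological coefficient of variation 15.4%). The 5 comparisons were tested with the edgeR quasi-likelihood F-test (robust), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. They were challenge in water-history plants (W_JA against W_W), challenge in JA-history plants (JA_JA against JA_W), history without challenge (JA_W against W_W), history under challenge (JA_JA against W_JA) and the interaction (the challenge effect in JA-history plants minus that in water-history plants). Levels in the text are TMM-scaled CPM as mean ± SD, and log2 changes carry the SE derived from the F-test. Where a group had no read of a gene, a fold is given as the least that 3 reads over that group allow. Where it had 1 to 3 reads, the ratio of counts is given with its 95% Poisson interval, called the counting interval.

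The 26 gene lists were fixed before the data were examined, 24 of them by locus with 300 genes (278 tested) and 2 as all plastid-encoded or mitochondrion-encoded genes. Lists with 3 or more tested members were tested with camera on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, repeated with an estimated correlation, with fry beside it; the adjustment ran over the lists of a comparison. Members called are counted over all genes tested and again adjusted over the list alone. A list of transposable element genes was planned but not used here, since neither the tables nor the annotation marks such genes by type. The genes named in the text follow a rule fixed beforehand. It takes in each comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and no overlap between replicates (no overlap rule for the interaction). It adds up to 4 called members with the largest change of each list described, or the 2 with the smallest p where none was called, and 8 markers (VSP2, LOX2, MYC2, JAZ10, PDF1.2a, ORA59, PR1 and CYP79B2).

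The effect of history on JA-responsive genes was read across pairs of replicates: genes called with a fold over 2 between W_JA and W_W in replicates 1 and 2 were read in replicates 3 and 4, and the reverse, so that no library both chose and tested a gene. The analysis was tested on simulated data in which 200 genes were changed in each comparison, 50 at each of 4 sizes. Of genes changed 2-fold it called 74% in the challenge of water-history plants, 68% in that of JA-history plants, 74% and 72% for history without and under challenge, and 56% for the interaction. Of genes changed 1.5-fold it called 44%, 44%, 38%, 50% and 12%, so changes of that size were often missed. False calls made up 8.77%, 3.77%, 6.36%, 7.76% and 3.75% of the calls. Only 200 genes differed in each simulation, while 18.4% (interaction) to 64.9% (history without challenge) of genes were called in the data. The adjustment over genes is less strict where more genes change, so these shares need not carry over to the data.

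The alternatives tried were DESeq2, RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 4 samples, fits of only the 2 groups compared, the replicate number as a block, counts thinned to the smallest library, a fold over 2, a threshold of 0.01, other pairs of replicates, correlation over called genes alone and each library left out in turn. After the data were seen, scaling by library totals only, leaving out 2 libraries that stood apart, reading the lists without challenge, and the ratio of history effects over every pairing of replicates were added. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Reads shared between close paralogs (PDF1.2a, PDF1.2b and PDF1.2c, VSP1 and VSP2, the LHCB1 and RBCS genes) could not be followed from counts per gene.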

Results

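The libraries separated first by seedling history and then by adult challenge. Principal components were taken over the 19224 genes tested, 3 weeks after the seedling spray. The first component (56.1% of the variance) placed all 8 JA-history libraries on one side and all 8 water-history libraries on the other. The second (26.5%) parted challenged from unchallenged libraries within both histories, and the third held 3.78%. A difference in growth place or infection that followed history would be confounded with the spray, here and in every comparison of histories below. W_W replicate 4 and JA_W replicate 1 lay nearest to the other history among unchallenged libraries. The 10 most abundant genes took 6.91% to 8.48% of the reads in W_W and 9.73% to 11.1% in JA_JA. Values below are TMM-scaled CPM as mean ± SD (n = 4) and log2 changes ± SE, and each gene said to have risen or fallen passed the adjusted p threshold of 0.05 in edgeR.

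**Figure D1:**
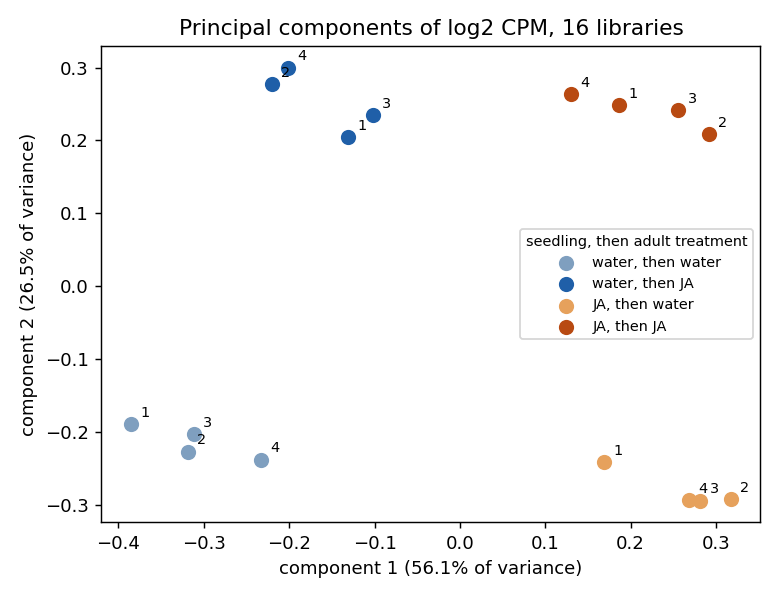
Principal component scores of the 16 libraries, first component (56.1% of the variance) against second (26.5%), 1 point per library and 4 per group. History separates along the first axis and challenge along the second.

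Numbers of called genes differed in the same way. The challenge raised 2674 genes and lowered 2473 in water-history plants (707 and 759 by more than 2-fold), and raised 2964 and lowered 3174 in JA-history plants (936 and 556). Between histories without challenge 12471 genes differed, 64.9% of those tested, with 6497 higher and 5974 lower in JA-history plants (1566 and 2573 by more than 2-fold). Under challenge, 3630 were higher and 4080 lower (542 and 1435). The challenge effect differed between histories for 3539 genes, 1539 more positive and 2000 more negative in JA-history plants (529 and 343 by more than 2-fold). The balance of the directions rested on scaling: with library totals only, genes higher made up 30.9% of calls in place of 52.0% for the challenge of water-history plants, 32.1% in place of 48.3% for that of JA-history plants and 32.7% in place of 47.1% for history under challenge, and upper-quartile scaling made the last 59.9%. For history without challenge, library totals gave 5117 higher and 6944 lower, and upper-quartile scaling 7368 and 5280. The majority direction of the interaction turned with DESeq2 (2169 and 1998), with RLE scaling (1792 and 1657) and without JA_JA replicate 2 (1661 and 1346) or 3 (1575 and 1389). With DESeq2 it also turned for the challenge of water-history plants (2613 and 2920) and of JA-history plants (3312 and 3162), so no majority direction is claimed for any comparison. Without JA_W replicate 2 the interaction counts were 1012 and 1332.

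**Figure D2:**
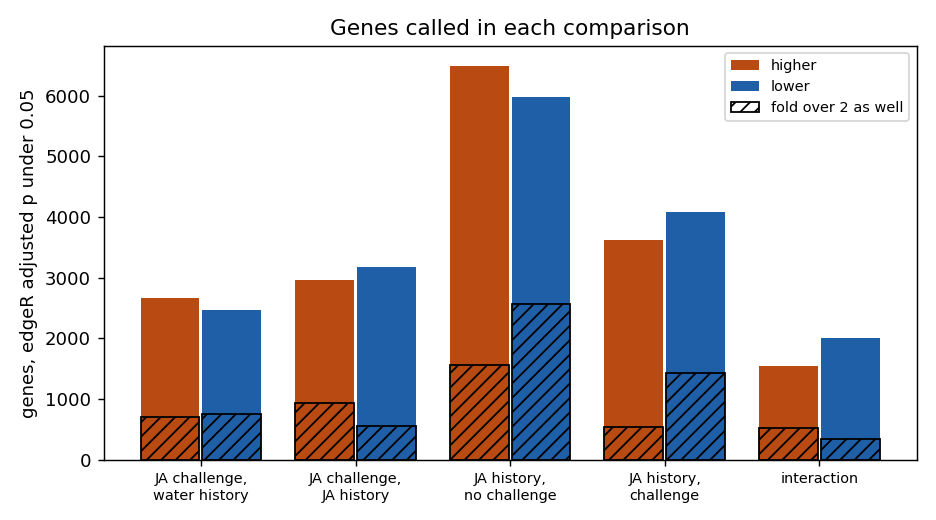
Numbers of genes called higher (left bar of each pair) and lower (right bar) at an adjusted p under 0.05 in edgeR for each of the 5 comparisons. The part over 2-fold is hatched. History without challenge has the tallest bars, 6497 and 5974.

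JA challenge of water-history plants raised the storage protein genes VSP2 and VSP1 and the terpene synthase gene TPS10 from low levels. VSP2, a vegetative storage protein and wound marker, went from 3.69 ± 1.27 CPM in W_W to 2735 ± 406 in W_JA (SD, n = 4), 742-fold (log2 9.54 ± 0.32, edgeR adjusted p = 1.36e-12), and VSP1 from 0.779 ± 0.304 to 1160 ± 153, 1485-fold (10.54 ± 0.36). TPS10, a terpene synthase, rose 886-fold to 82.3 ± 12.9 CPM. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, had no read in W_W and 13.3 ± 3.42 CPM in W_JA, a rise of at least 646-fold. A TRAF-like gene, AT5G26260, and an oxygenase gene, AT1G14120, each had 1 read in W_W, with count ratios of 2107 (95% counting interval 378 to 83250) and 1144 (205 to 45240). Among the falls, KCS12, a fatty acid elongation enzyme, dropped from 27.1 ± 14.3 to 1.75 ± 0.940 CPM (15.6-fold), WAG1, a protein kinase, from 2.92 ± 0.491 to 0.227 ± 0.0700 (12.7-fold) and GLIP1, a secreted lipase, from 3.54 ± 0.461 to 0.271 ± 0.145 (12.9-fold). The oxygenase AT1G48980 fell 17.2-fold, CYP96A5 13.9-fold and the berberine-bridge type gene AT1G26410 12.3-fold.

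Jasmonate synthesis, turnover and repression genes rose together in water-history plants. Of 15 tested JA biosynthesis genes 12 rose (12 adjusted over the list alone, median log2 1.04, camera adjusted p = 4.12e-10), among them LOX2, the plastid lipoxygenase of the pathway, from 2098 ± 532 to 20371 ± 1371 CPM (9.71-fold), and the cyclase AOC1 from 82.0 ± 22.9 to 930 ± 30 (11.3-fold). AOS, allene oxide synthase, rose 5.99-fold and AOC2 5.62-fold. All 9 JA catabolism genes rose (9 adjusted over the list alone, median 5.23, camera adjusted p = 4.07e-13), with the JA oxidase JOX3 at 2.30 ± 0.987 and 293 ± 108 CPM (128-fold) and the sulfotransferase ST2A at 1.5 ± 0.871 and 180 ± 46.5 (120-fold). CYP94B3, a jasmonoyl-isoleucine hydroxylase, rose 50.2-fold; its relative CYP94B1 had 2 reads in W_W and a count ratio of 246 (67.6 to 2034). Of 13 JAZ repressors 11 rose (11 adjusted over the list alone, median 1.82, camera adjusted p = 6.46e-12): JAZ10 23.6-fold to 24.0 ± 8.29 CPM, JAZ8 20.3-fold and JAZ5 9.54-fold. Of 10 JA transcription factor genes 7 rose (7, and 1 fell, adjusted over the list alone, camera adjusted p = 0.000635, adjusted p = 0.215 with an estimated correlation), with NAC019 up 10.1-fold and the repressor JAM1 2.40-fold. MYC2, the marker for the master regulator of this branch, was listed with no read in any library and was not tested.

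Outputs of the 2 defence branches of jasmonate signalling were read apart. All 15 MYC-branch outputs rose (15 adjusted over the list alone, median log2 6.25, camera adjusted p = 2.31e-27); BSMT1, a benzoate and salicylate methyltransferase, had 3 reads in W_W and a count ratio of 848 (290 to 4117). Of 10 ERF-branch outputs 3 rose and 3 fell (4 and 3 adjusted over the list alone). ORA59, the regulator of that branch, fell from 3.25 ± 0.837 to 0.266 ± 0.192 CPM (12.1-fold, edgeR adjusted p = 8.63e-06) and ERF1 fell 3.84-fold. THI2.1, a thionin, rose from 2 reads to 2.07 ± 0.508 CPM (count ratio 150, 41.0 to 1242). The defensin PDF1.2a stood at 2.25 ± 0.420 and 5.32 ± 2.35 CPM (edgeR adjusted p = 0.0639). Of 23 salicylic acid (SA) pathway genes 2 rose and 6 fell (3 and 6 adjusted over the list alone), with NIMIN1 down 3.95-fold and NIMIN2 3.45-fold, both NPR1-interacting proteins. PR1, an SA marker, stood at 500 ± 256 and 530 ± 362 CPM (edgeR adjusted p = 0.933). Of 9 ethylene pathway genes 2 fell, the synthase gene ACS6 by 2.33-fold and the F-box gene EBF2 by 1.70-fold (2 adjusted over the list alone).

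Most aliphatic glucosinolate and pigment genes rose as well, as did some indole glucosinolate genes. Of 21 aliphatic glucosinolate genes 17 rose (20 adjusted over the list alone, median log2 0.95, camera adjusted p = 2.30e-10, adjusted p = 0.234 with an estimated correlation), led by FMOGS-OX1 (11.8 ± 3.64 to 38.1 ± 5.83 CPM, 3.23-fold) and CYP79F2 (2.70-fold). Of 20 indole glucosinolate genes 9 rose and 5 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.00673, adjusted p = 0.352 with an estimated correlation). IGMT5, an indole glucosinolate methyltransferase, rose 112-fold to 94.1 ± 15.7 CPM and CYP81F4 from no read by at least 99.4-fold, while CYP81F2 fell 4.98-fold; the marker CYP79B2 stood at 77.8 ± 18.9 and 112 ± 36.9 CPM (edgeR adjusted p = 0.0906). Of 9 tryptophan synthesis genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0130, adjusted p = 0.352 with an estimated correlation), with PAT1 up 2.13-fold. Of 7 glucosinolate breakdown genes 4 rose (5, and 1 fell, adjusted over the list alone, camera adjusted p = 0.000189); the nitrile specifier NSP1 went from 6.16 ± 0.556 to 278 ± 27.2 CPM (45.2-fold). Of 15 anthocyanin and flavonoid genes 11 rose (11 adjusted over the list alone, median 3.09, camera adjusted p = 1.87e-08), among them UGT79B1 (24.7-fold) and the regulators GL3 (25.6-fold) and TT8 (from no read, at least 11.0-fold).

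Stress, clock and handling lists held called genes too. Of 15 abscisic acid (ABA) response genes 8 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00286, adjusted p = 0.352 with an estimated correlation), with RD20, a caleosin, up 6.10-fold and COR15A 3.71-fold. Of 14 circadian clock genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.0921 with an estimated correlation), with the evening genes LUX up 3.69-fold and PRR5 3.01-fold. Of 7 touch and early wound genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with WRKY33 down 2.08-fold, and of 8 senescence genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), with NAP, a senescence regulator, down 2.32-fold. In the DNA methylation and small RNA machinery, 2 of 21 rose and 1 fell (2 and 1 adjusted over the list alone); AGO2 fell 1.79-fold. Medians lay at 0.02 for 22 photosynthesis genes, -0.15 for 6 dividing cell markers and 0.11 for 3 phloem companion cell markers. The potassium channel KAT1, 1 of 3 guard cell markers, rose 1.93-fold (1 adjusted over the list alone) and SOC1, a flowering regulator, 1.62-fold. The fold of CYP96A5 moved by more than 1.5 times in at least 1 alternative.

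**Figure D3:**
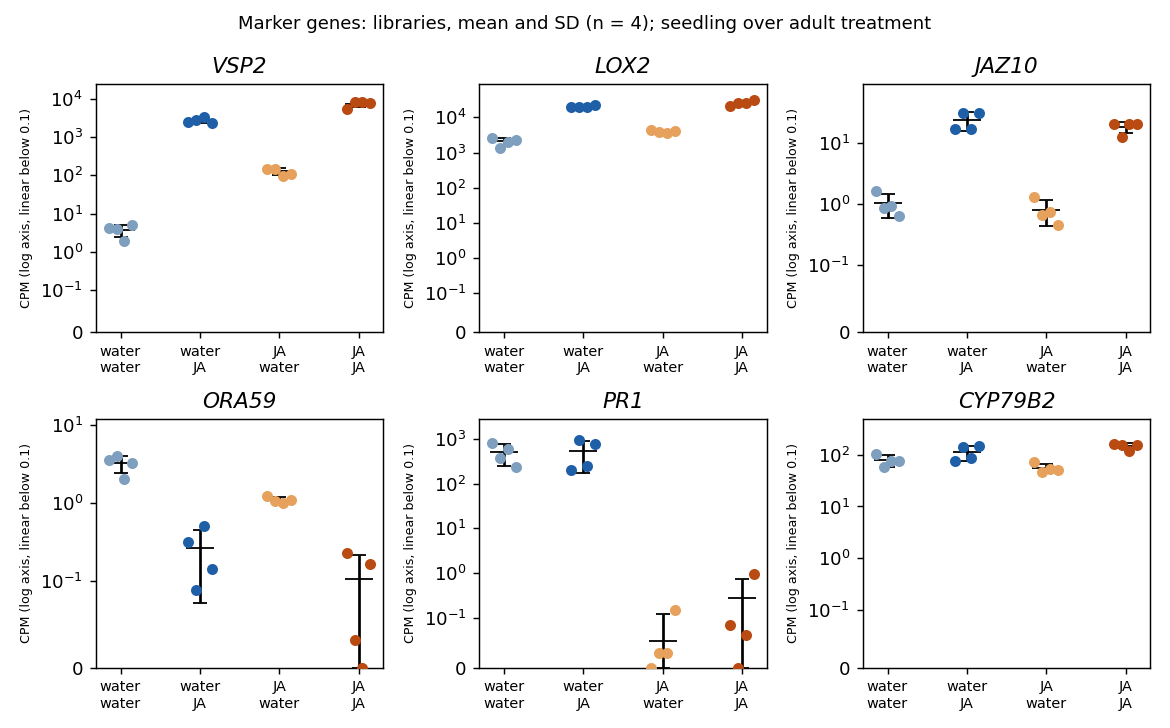
Levels of 6 marker genes in TMM-scaled CPM (log axis, linear near 0), 1 point per library with the group mean and SD, n = 4 per group. VSP2 has means of 3.69, 2735, 126 and 7436 CPM in W_W, W_JA, JA_W and JA_JA, and PR1 has 500, 530, 0.0528 and 0.282.

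JA challenge of JA-history plants raised VSP2, VSP1 and the terpene synthase TPS10 to higher final levels than in water-history plants, from a higher start. VSP2 went from 126 ± 26.4 CPM in JA_W to 7436 ± 1432 in JA_JA (SD, n = 4), 59.1-fold (log2 5.88 ± 0.27, edgeR adjusted p = 7.93e-11), and VSP1 from 10.1 ± 3.73 to 3072 ± 550 (305-fold). RAP2.6, an AP2/ERF factor, rose 705-fold to 23.3 ± 5.25 CPM, TPS10 587-fold to 213 ± 45.5 and ILL5, an amidohydrolase-like gene, 600-fold to 134 ± 18.3. CYP81F4 and MSRB7, a methionine sulfoxide reductase, had no read in JA_W and rose by at least 209-fold and 189-fold; PYK10 had 2 reads in JA_W and a count ratio of 885 (95% counting interval 245 to 7311). Lower after challenge were LBD1, a LOB-domain factor (2.1 ± 0.501 to 0.0657 ± 0.0604 CPM, 31.4-fold), WSD1, a wax ester synthase (7.03 ± 1.54 to 0.381 ± 0.207, 18.6-fold), and GolS2, a galactinol synthase (3.91 ± 0.854 to 0.280 ± 0.111, 13.6-fold). The lipid transfer gene LTP3 fell 17.6-fold, AT1G65500 16.3-fold and the GDSL lipase gene AT4G28780 11.0-fold.

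Jasmonate pathway genes responded in JA-history plants too. Of 15 JA biosynthesis genes 12 rose (12 adjusted over the list alone, median log2 1.33, camera adjusted p = 1.39e-10), with LOX2 at 3903 ± 338 and 25409 ± 3880 CPM (6.51-fold), AOC1 up 11.4-fold, OPR3 6.01-fold and AOC2 4.88-fold. All 9 JA catabolism genes rose (9 adjusted over the list alone, median 7.30, camera adjusted p = 5.75e-14): JOX3 567-fold from 0.476 ± 0.277 to 276 ± 98.4 CPM, ST2A 423-fold, CYP94B3 376-fold and JOX4 347-fold. Of 13 JAZ repressors 10 rose (11 adjusted over the list alone, camera adjusted p = 2.42e-10, adjusted p = 0.0600 with an estimated correlation), with JAZ7 up 38.7-fold, JAZ10 23.1-fold and JAZ8 10.8-fold. Of 10 JA transcription factor genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00234, adjusted p = 0.253 with an estimated correlation), with NAC019 up 9.34-fold and RD26 2.97-fold. All 15 MYC-branch outputs rose (15 adjusted over the list alone, median 6.11, camera adjusted p = 1.51e-22), BSMT1 by 157-fold. Of 10 ERF-branch outputs 3 rose and 1 fell (3 and 1 adjusted over the list alone): THI2.1 rose 47.9-fold, ORA59 fell 9.78-fold from 1.11 ± 0.0995 CPM, and PDF1.2a rose 3.79-fold to 0.918 ± 0.867, a call that several alternatives ended (edgeR adjusted p = 0.0440).

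Some SA pathway genes rose after challenge in JA-history plants, from low levels. Of 23 members 12 rose and 1 fell (12 and 1 adjusted over the list alone, median log2 1.64, camera adjusted p = 2.85e-06, adjusted p = 0.270 with an estimated correlation). GRXC9, a glutaredoxin, went from 0.243 ± 0.236 to 9.68 ± 6.42 CPM (38.3-fold), WRKY54 from 5.53 ± 2.71 to 48.4 ± 23.7 (8.76-fold) and SARD1, a regulator of SA synthesis, from 2.63 ± 0.413 to 17.6 ± 8.65 (6.70-fold). PR1 stood at 0.0528 ± 0.0674 and 0.282 ± 0.464 CPM (edgeR adjusted p = 0.355). Of 9 ethylene pathway genes 3 rose (3 adjusted over the list alone), with EBF1 up 1.29-fold. Of 8 senescence genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.000598, adjusted p = 0.155 with an estimated correlation), with SEN1 up 5.42-fold and PPH, a pheophytinase, 2.89-fold.

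Most tryptophan synthesis and indole glucosinolate genes rose in JA-history plants. Of 9 tryptophan synthesis genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, median log2 1.22, camera adjusted p = 6.81e-07, adjusted p = 0.0600 with an estimated correlation): TSA1 went from 47.6 ± 2.75 to 285 ± 21.4 CPM (5.99-fold) and PAT1 rose 4.53-fold. Of 20 indole glucosinolate genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 3.84e-08, adjusted p = 0.0600 with an estimated correlation), with IGMT5 up 41.9-fold, IGMT1 11.5-fold, MYB122, a regulator, from no read by at least 8.23-fold, and CYP79B2, which opens the pathway, from 55.6 ± 11.6 to 145 ± 19.1 CPM (2.61-fold). Of 21 aliphatic members 3 rose (1 adjusted over the list alone), among them MYB76 1.94-fold. Of 7 breakdown genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.000456), with NSP1 up 24.8-fold and ESM1, an epithiospecifier modifier, down 2.53-fold. Of 15 anthocyanin and flavonoid genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.270 with an estimated correlation), with UGT79B1 up 18.4-fold and DFR, dihydroflavonol reductase, 8.26-fold.

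Remaining lists went both ways in JA-history plants. Of 15 ABA response genes 6 rose and 4 fell (6 and 4 adjusted over the list alone), with RD20 up 4.15-fold and RD22 down 2.55-fold. Of 14 clock genes 7 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.253 with an estimated correlation), with RVE1 up 3.75-fold and PRR5 3.14-fold. Of 7 touch genes 3 rose and 1 fell (3 and 1 adjusted over the list alone): ORA47 rose 2.21-fold and TCH2 fell 2.16-fold. In the DNA methylation and small RNA machinery 6 of 21 fell (7 adjusted over the list alone), among them the glycosylase DML3 1.86-fold, the methyltransferase CMT3 1.74-fold and the remodeler DDM1 1.73-fold. RBCS1B, a Rubisco small subunit gene, fell 1.95-fold as 1 of 22 photosynthesis genes (1 adjusted over the list alone), and SOC1 rose 1.93-fold. Plastid-encoded transcripts had a median of 0.22 over 63 genes (camera adjusted p = 0.0135, adjusted p = 0.548 with an estimated correlation). In at least 1 alternative the folds of AT1G65500, BSMT1, CYP94B3, GRXC9, JAZ8, ORA59, PDF1.2a and THI2.1 moved by more than 1.5 times.

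The 2 challenge responses overlapped in part. Genes raised in both histories numbered 1184, where independence would give 412, and genes lowered in both 840 (408), while 321 were called in opposite directions. Across all 19224 genes the log2 changes, which share no library, correlated at Pearson r = 0.69 and Spearman rho = 0.32; genes are not independent, so no p is given. Within replicates 1 and 2 the Pearson r was 0.62, and within replicates 3 and 4 it was 0.64.

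Without challenge, SA pathway transcripts of JA-history plants lay far below those of water-history plants. PR1 stood at 500 ± 256 CPM in W_W and 0.0528 ± 0.0674 in JA_W (SD, n = 4), 9075-fold lower (log2 -13.15 ± 1.06, edgeR adjusted p = 1.73e-07). That fold rests on few reads, 5 of them in JA_W replicate 4, without which the log2 change of PR1 was -14.40. All 23 tested SA pathway genes were lower (23 adjusted over the list alone, median log2 -4.09, camera adjusted p = 7.04e-13, adjusted p = 0.335 with an estimated correlation). ALD1, which makes the pipecolate precursor of systemic resistance, went from 43.5 ± 17.8 to 0.337 ± 0.289 CPM (125-fold), WRKY62 from 3.86 ± 1.70 to 0.0290 ± 0.0336 (117-fold) and WRKY38 from 16.0 ± 2.34 to 0.177 ± 0.132 (88.6-fold). Among the largest falls, the AAA-type ATPase gene AT3G28510 was 1201-fold lower and the oxygenase gene AT4G10500, from 202 ± 71.3 to 0.795 ± 0.526 CPM, 255-fold. ARD3, an acireductone dioxygenase, had 3 reads in JA_W against 7314 in W_W (ratio 0.000438, 95% counting interval 9.04e-05 to 0.00128), AT4G05540 had 1 read (ratio 0.00146, 3.69e-05 to 0.00815), and AT2G44240 had none, at least 137-fold lower.

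In the other direction, VSP2, a Kunitz inhibitor gene and most listed anthocyanin and flavonoid genes stood higher in unchallenged JA-history plants. VSP2 was 34.2-fold higher (126 ± 26.4 against 3.69 ± 1.27 CPM), the Kunitz inhibitor gene AT1G73325 51.9-fold (7.30 ± 5.79 against 0.139 ± 0.0957), CSLA01, a glucomannan synthase, 38.4-fold (17.3 ± 5.30 against 0.447 ± 0.0275) and CHS, chalcone synthase, 20.9-fold (149 ± 41.9 against 7.15 ± 2.98, edgeR adjusted p = 9.68e-08). AT3G61920 was 16.5-fold and the nudix hydrolase NUDT24 15.9-fold higher. Of 15 anthocyanin and flavonoid genes 12 were higher (13 adjusted over the list alone, median log2 3.40, or 2.98 with TT8 at its bound, camera adjusted p = 3.39e-05, adjusted p = 0.335 with an estimated correlation). TT8 rose from no read by at least 5.34-fold, F3H had 2 reads in W_W and a ratio of 35.3 (9.38 to 297), and 5MAT had 1 and a ratio of 72.7 (12.6 to 2912). Of 21 aliphatic glucosinolate genes 20 were higher and 1 lower (20 and 1 adjusted over the list alone, median 1.27, camera adjusted p = 1.18e-05, adjusted p = 0.517 with an estimated correlation), with FMOGS-OX3 at 18.6 ± 6.86 and 61.6 ± 8.50 CPM (3.31-fold), the regulator MYB29 3.22-fold and GSTU20 3.13-fold higher. Of 7 breakdown genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone), the myrosinase TGG2 by 2.61-fold.

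Jasmonate genes were split by history without challenge, among 64.9% of all genes called. Of these lists camera called only MYC-branch outputs. Its adjusted p at the preset correlation was 0.816 for JA biosynthesis, 0.0694 for JA catabolism, 0.596 for JAZ repressors and 0.283 for JA transcription factors. Of 15 MYC-branch outputs 10 were higher and 3 lower in JA-history plants (10 and 3 adjusted over the list alone, median log2 1.18, camera adjusted p = 0.0179, adjusted p = 0.511 with an estimated correlation). VSP1 was 12.9-fold higher, while TPS04, a geranyllinalool synthase, fell from 6.80 ± 3.82 to 0.185 ± 0.211 CPM (35.0-fold) and the aminotransferase TAT3 from 408 ± 145 to 16.9 ± 9.46 (24.1-fold). Of 15 JA biosynthesis genes 5 were higher and 6 lower (5 and 6 adjusted over the list alone): AOS 2.49-fold and LOX2 1.86-fold higher, AOC3 4.75-fold and ACX1 2.24-fold lower. Of 9 JA catabolism genes 5 were lower (5 adjusted over the list alone), JOX4 11.4-fold and JOX3 4.72-fold. Of 13 JAZ repressors 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with JAZ9 2.85-fold higher and JAZ7 4.77-fold lower; JAZ10 stood at 1.02 ± 0.436 and 0.789 ± 0.362 CPM (edgeR adjusted p = 0.459). Of 10 JA transcription factor genes 2 were higher and 6 lower (2 and 6 adjusted over the list alone), MYC4 by 1.96-fold higher and RD26 2.46-fold lower. Of 10 ERF-branch outputs 1 was higher and 7 lower (2 and 7 adjusted over the list alone, median -3.68). That list was not called (camera adjusted p = 0.0598, adjusted p = 0.511 with an estimated correlation). ERF1 was 23.4-fold lower, the chitin-binding PR4 22.9-fold (146 ± 26.7 to 6.38 ± 2.31 CPM), PDF1.2b 18.1-fold, PDF1.2a 9.13-fold and ORA59 2.93-fold. PDF1.3 had 1 read in JA_W (ratio 0.00869, 0.000218 to 0.0493).

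Ethylene, senescence, touch and tryptophan genes were mostly lower in unchallenged JA-history plants. Of 9 ethylene pathway genes 8 were lower (8 adjusted over the list alone, camera adjusted p = 0.00430, adjusted p = 0.366 with an estimated correlation), ACS2 4.79-fold and ACS6 3.28-fold. Of 8 senescence genes 7 were lower (7 adjusted over the list alone, median log2 -1.98, camera adjusted p = 0.00461, adjusted p = 0.371 with an estimated correlation): ORE1, a NAC regulator, 19.9-fold, SEN1 13.6-fold and NAP 8.26-fold (25.7 ± 4.94 to 3.10 ± 0.601 CPM). Of 7 touch and early wound genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0424, adjusted p = 0.511 with an estimated correlation), with WRKY40 11.0-fold and the calmodulin-like TCH3 10.9-fold lower. Of 9 tryptophan synthesis genes 2 were higher and 6 lower (2 and 6 adjusted over the list alone), ASB1 3.46-fold and TSA1 3.18-fold lower. Camera did not call this list (adjusted p = 0.0574, adjusted p = 0.594 with an estimated correlation). Of 20 indole glucosinolate genes 5 were higher and 9 lower (5 and 9 adjusted over the list alone), with MYB51 12-fold lower (58.1 ± 9.03 to 4.84 ± 1.34 CPM) and MYB122 at least 38.7-fold; CYP79B2 stood at 77.8 ± 18.9 and 55.6 ± 11.6 CPM (edgeR adjusted p = 0.0651).

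Some growth-related and cell type markers were higher in JA-history plants, among 64.9% of all genes called. Of 22 photosynthesis genes 9 were higher in JA-history plants (9 adjusted over the list alone, median log2 0.35, camera adjusted p = 0.0217, adjusted p = 0.743 with an estimated correlation), with RBCS1B 2.6-fold and LHCB1.2 1.49-fold. Of 6 dividing cell markers 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.283), CDKB1;1 2.24-fold and CDKB2;1 1.92-fold; the trichome regulator GL2 was 2.13-fold and the guard cell factor FAMA, 1 of 2 guard cell markers higher of 3 (2 adjusted over the list alone), 1.53-fold higher. The phloem companion cell median was 0.02, and SOC1 was 1.48-fold lower. Of 15 ABA response genes 7 were higher and 4 lower (7 and 4 adjusted over the list alone): COR15A rose from 156 ± 60.0 to 942 ± 153 CPM (6.03-fold) and RD29B fell 9.32-fold. Of 14 clock genes 6 were higher and 3 lower (6 and 3 adjusted over the list alone), LUX 2.69-fold higher and TOC1 2.48-fold lower. Of 21 DNA methylation and small RNA genes 8 were higher and 6 lower (8 and 6 adjusted over the list alone), with DDM1 2.37-fold and CMT2 2.13-fold higher and DML2, a demethylase, 2.34-fold lower. Medians were 0.06 over 63 plastid-encoded and -0.28 over 18 mitochondrion-encoded genes. Folds that moved by more than 1.5 times in at least 1 alternative were those of ACS2, ALD1, AOC3, AT1G73325, ERF1, JOX4, NUDT24, ORE1, PR1, TPS04, WRKY38 and WRKY40.

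**Figure D4:**
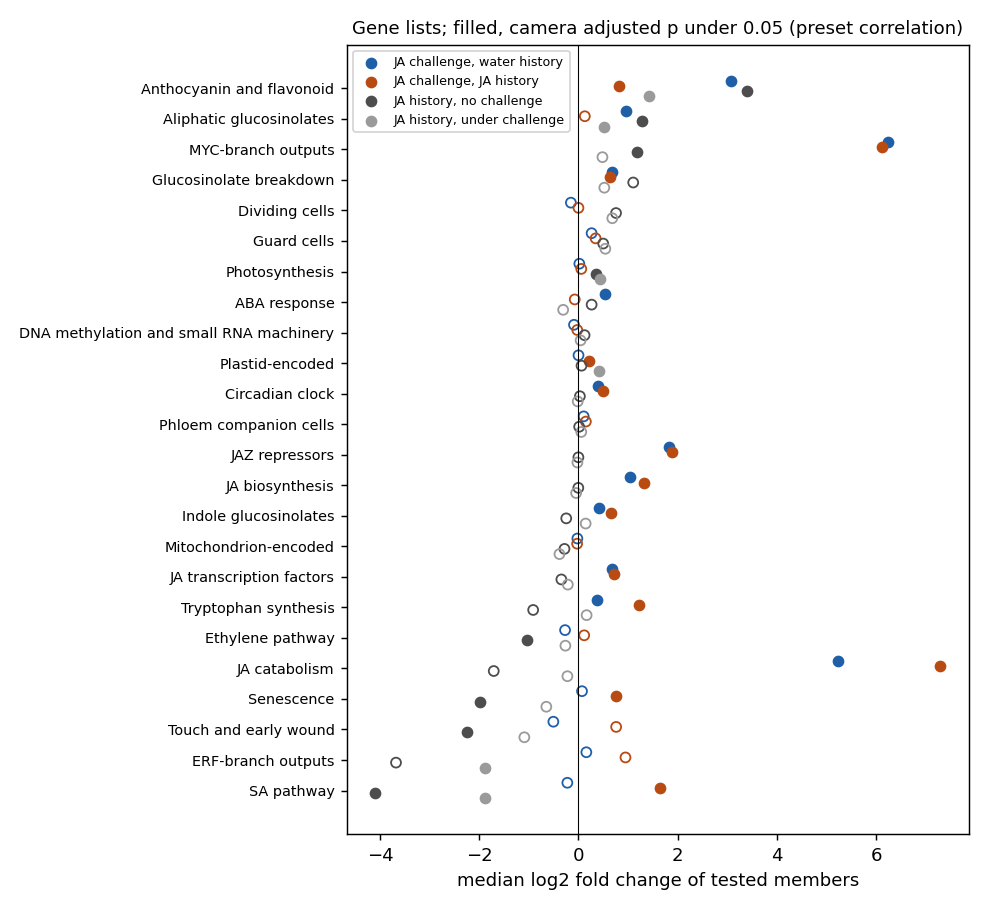
Median log2 change of each gene list in the 4 pairwise comparisons, with filled points where camera at the preset correlation gave an adjusted p under 0.05; with an estimated correlation all 8 calls for history without challenge, all 6 under challenge, 6 of 12 for challenge of water-history plants and 9 of 13 for that of JA-history plants are lost. The SA pathway median is -4.09 for history without challenge (adjusted p = 0.335 with an estimated correlation) and 1.64 for challenge of JA-history plants (0.270).

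Under challenge, JA-history plants kept lower SA and higher anthocyanin transcripts than water-history plants. PR1 stood at 530 ± 362 CPM in W_JA and 0.282 ± 0.464 in JA_JA (SD, n = 4), 1934-fold lower (log2 -10.92 ± 0.91, edgeR adjusted p = 2.79e-06; -13.24 without JA_JA replicate 4), and the glucanase PR2 at 3493 ± 1727 and 94.2 ± 54.3 (37.1-fold). FMO1, a monooxygenase of systemic resistance, was 64.3-fold, ALD1 46.6-fold and AT3G28510 309-fold lower. ARD3 had 1 read in JA_JA (ratio 0.000402, 95% counting interval 1.02e-05 to 0.00224), AT4G05540 had 1 (0.00204, 5.16e-05 to 0.0114), EDA36 had 2 (0.00623, 0.000752 to 0.0227), and AT4G10860 had none, at least 239-fold lower. Higher were 5MAT, an anthocyanin acyltransferase (0.438 ± 0.446 to 6.29 ± 2.30 CPM, 14.1-fold), TT19, a glutathione transferase (0.492 ± 0.291 to 5.11 ± 2.01, 10.3-fold), and LDOX, leucoanthocyanidin dioxygenase (9.16-fold). AT4G02850 was 9.28-fold, the germin GER3 7.11-fold and the epidermal gene PDF1 6.50-fold higher.

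Several lists kept under challenge the direction seen without it, while the medians of others turned. Without and under challenge these were -0.91 and 0.17 for tryptophan synthesis, 0.27 and -0.31 for ABA response, and -0.25 and 0.15 for indole glucosinolates. Of 23 SA pathway genes 20 were lower (20 adjusted over the list alone, median log2 -1.88, camera adjusted p = 3.45e-13, adjusted p = 0.317 with an estimated correlation). Of 15 anthocyanin and flavonoid genes 12 were higher (13 adjusted over the list alone, median 1.43, camera adjusted p = 3.04e-06, adjusted p = 0.240 with an estimated correlation). Of 22 photosynthesis genes 9 were higher (16 adjusted over the list alone, camera adjusted p = 0.000157, adjusted p = 0.649 with an estimated correlation), with LHCB1.2 1.52-fold and LHCB3 1.46-fold. Of 21 aliphatic glucosinolate genes 8 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.00877, adjusted p = 0.682 with an estimated correlation), with MYB76 2.2-fold higher and MAM3, a chain elongation enzyme, 6.07-fold lower. Of 10 ERF-branch outputs 1 was higher and 5 lower (1 and 6 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.529 with an estimated correlation): PDF1.2c 21.0-fold, PR4 11.0-fold and PDF1.2a 5.69-fold lower, with ORA59 at 0.266 ± 0.192 and 0.107 ± 0.109 CPM (edgeR adjusted p = 0.135). Plastid-encoded genes were higher for 19 of 63 and lower for 2 (16 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.000331, adjusted p = 0.593 with an estimated correlation), and the mitochondrion-encoded median was -0.38.

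Jasmonate genes went both ways between histories under challenge. VSP2 was 2.72-fold and VSP1 2.65-fold higher in JA_JA, and TAT3 10.4-fold and TPS04 7.67-fold lower; of 15 MYC-branch outputs 7 were higher and 2 lower (7 and 2 adjusted over the list alone). LOX2 stood at 20371 ± 1371 and 25409 ± 3880 CPM (edgeR adjusted p = 0.144) and JAZ10 at 24.0 ± 8.29 and 18.5 ± 4.1 (edgeR adjusted p = 0.276). Of 15 JA biosynthesis genes 5 were higher and 4 lower (5 and 4 adjusted over the list alone), with LOX3 at 139 ± 30.9 and 50.0 ± 27.3 CPM (2.79-fold lower) and AOC3 2.32-fold lower. Of 10 JA transcription factor genes 1 was higher and 6 lower (1 and 6 adjusted over the list alone), NAC055 4.6-fold and NAC019 2.88-fold lower. Of 20 indole glucosinolate genes 7 were higher and 6 lower (8 and 6 adjusted over the list alone), CYP81F4 2.26-fold higher and MYB51 3.38-fold lower, with CYP79B2 at 112 ± 36.9 and 145 ± 19.1 CPM (edgeR adjusted p = 0.182). TSA1 and PAI1, 2 of 9 tryptophan synthesis genes, were 1.46-fold and 1.41-fold higher (2 adjusted over the list alone), and the myrosinases TGG2 and TGG1 2.83-fold and 2.21-fold, among 3 of 7 breakdown genes higher and 1 lower (5 and 2 adjusted over the list alone).

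Some senescence, touch and growth markers differed between histories under challenge, among 40.1% of all genes called, and camera called none of these lists (adjusted p = 0.0789 for senescence, 0.0815 for touch and 0.0935 for dividing cells). Of 8 senescence genes 1 was higher and 4 lower (1 and 5 adjusted over the list alone), ORE1 21.5-fold and SAG13 11.6-fold lower. Of 7 touch genes 1 was higher and 4 lower (1 and 4 adjusted over the list alone), TCH3 4.02-fold and WRKY33 2.76-fold lower, and EIN3, 1 of 2 ethylene genes lower of 9 (2 adjusted over the list alone), was 1.39-fold lower. Of 6 dividing cell markers 3 were higher (3 adjusted over the list alone), CYCB1;2 2.66-fold and the cytokinesis syntaxin KNOLLE 2.49-fold. Of 3 guard cell markers 2 were higher and 1 lower (2 and 1 adjusted over the list alone), FAMA 1.62-fold higher and KAT1 1.69-fold lower, and GL2 was 1.5-fold higher. Of 15 ABA response genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone), RD29B 5.6-fold lower and COR15A 1.99-fold higher. Of 14 clock genes 3 were higher and 2 lower (4 and 3 adjusted over the list alone), LUX 1.73-fold higher and TOC1 1.52-fold lower, and of 21 DNA methylation and small RNA genes 8 were higher and 3 lower (8 and 4 adjusted over the list alone), CMT2 1.61-fold higher and DME 1.46-fold lower. For 5MAT, AT3G28510, LDOX, PDF1.2a, PDF1.2c, PR1, SAG13 and TPS04 the fold moved by more than 1.5 times in at least 1 alternative.

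The 2 history effects pointed the same way for most called genes. Genes higher in JA-history plants both without and under challenge numbered 2981, where independence would give 1227, and genes lower in both 3572 (1268), against 92 in opposite directions. Their log2 changes correlated at Pearson r = 0.86 and Spearman rho = 0.79 across genes.

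The interaction showed where the challenge response differed between histories; a positive value means a more positive response in JA-history plants. VSP2 had a difference of -3.65 ± 0.33 (edgeR adjusted p = 1.05e-05): it rose 742-fold in water-history plants and 59.1-fold in JA-history plants, and ended higher in the latter. CSLA01 went from 0.447 ± 0.0275 to 188 ± 53.2 CPM with water history and from 17.3 ± 5.30 to 327 ± 44.1 with JA history (SD, n = 4; -4.47 ± 0.35), and AT1G73325 gave -5.14 ± 0.72. LTP3 gave -4.76 ± 1.33, and LTP4 -6.22 ± 1.95, both calls that alternatives ended. Among called genes with a mean of at least 1 CPM, the most positive was LAS1, lanosterol synthase (4.82 ± 0.70, edgeR adjusted p = 0.000601). LAS1 stood at 5.30 ± 1.91 and 48.4 ± 21.5 CPM with water history and 0.0666 ± 0.0450 and 18.0 ± 3.65 with JA history. Outside that limit, the highest fitted value of an indole glucosinolate gene was 6.43. In that list MYB122 and CYP81F4 had no read in JA_W, and a fitted difference that rests on such a group is not a measured size. The glutaredoxin GRXS13 fell from 27.2 ± 1.66 to 3.36 ± 0.350 CPM with water history against 0.191 ± 0.100 and 0.397 ± 0.294 with JA history (4.07 ± 0.53).

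Some SA, tryptophan and indole genes responded more positively in JA-history plants. Of 23 SA pathway genes 11 did so (13, and 1 more negatively, adjusted over the list alone, median 1.43, camera adjusted p = 9.78e-08, adjusted p = 0.419 with an estimated correlation), with NIMIN1 at 4.53 ± 0.51, GRXC9 at 4.05 ± 0.78 and NIMIN2 at 3.45 ± 0.59; PR1 had 2.23 ± 1.89 (edgeR adjusted p = 0.446). Of 9 tryptophan synthesis genes 6 were more positive and 2 more negative (7 and 2 adjusted over the list alone, camera adjusted p = 0.000315, adjusted p = 0.419 with an estimated correlation), with TSA1 at 2.21 ± 0.13 and ASB1 at 1.82 ± 0.20. Of 20 indole glucosinolate genes 6 were more positive and 2 more negative (7 and 2 adjusted over the list alone, camera adjusted p = 0.00531, adjusted p = 0.433 with an estimated correlation), MYB51 1.83 ± 0.41 and IGMT5 -1.42 ± 0.28; CYP79B2 had 0.86 ± 0.31 (edgeR adjusted p = 0.0657). Of 9 JA catabolism genes 4 were more positive (4 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.496 with an estimated correlation), JOX4 by 3.21 ± 0.65. Of 9 ethylene genes 3 (4 adjusted over the list alone, camera adjusted p = 0.00345, adjusted p = 0.419 with an estimated correlation) and of 8 senescence genes 3 (4 adjusted over the list alone, camera adjusted p = 0.00531, adjusted p = 0.419 with an estimated correlation) were more positive, ACS6 by 1.48 ± 0.22 and SEN1 by 2.99 ± 0.49. Of 7 touch genes 3 were more positive and 1 more negative (4 and 1 adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.433 with an estimated correlation), WRKY40 by 2.83 ± 0.71. ERF1, 1 of 10 ERF-branch outputs (1 adjusted over the list alone), had 3.53 ± 0.63.

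Some MYC-branch, aliphatic glucosinolate, anthocyanin and ABA genes had more negative responses in JA-history plants. Of 15 MYC-branch outputs 8 were more negative and 1 more positive (9 and 1 adjusted over the list alone, median -0.67, camera adjusted p = 0.00222, adjusted p = 0.419 with an estimated correlation), with VSP1 at -2.28 ± 0.38 and the myrosinase-binding MBP1 at -2.29 ± 0.36. Of 21 aliphatic glucosinolate genes 11 were more negative (15 adjusted over the list alone, median -0.76, camera adjusted p = 1.24e-06, adjusted p = 0.433 with an estimated correlation), with FMOGS-OX1 at -1.34 ± 0.30 and CYP79F1, at 106 ± 33.5, 231 ± 43.2, 259 ± 39.3 and 252 ± 47.2 CPM in W_W, W_JA, JA_W and JA_JA, at -1.17 ± 0.30. Of 15 anthocyanin and flavonoid genes 7 were more negative (7 adjusted over the list alone, camera adjusted p = 0.0246, adjusted p = 0.433 with an estimated correlation), CHS by -2.95 ± 0.43 and the regulator PAP1 by -2.69 ± 0.31. Of 15 ABA response genes 6 were more negative (6 adjusted over the list alone, camera adjusted p = 0.00845, adjusted p = 0.496 with an estimated correlation), RD29A by -1.95 ± 0.23. MYC4 (-1.17 ± 0.10), JAZ9 (-1.12 ± 0.19), AOS (-0.79 ± 0.19), LOX3 (-1.47 ± 0.40), NSP1 (-0.87 ± 0.16), KAT1 (-1.25 ± 0.24), RBCS1B (-1.21 ± 0.23), DDM1 (-0.66 ± 0.16) and GI (-0.49 ± 0.12) were more negative, and TOC1 (0.71 ± 0.19) more positive. LOX2 had -0.58 ± 0.24, JAZ10 -0.03 ± 0.51, PDF1.2a 0.68 ± 0.84 and ORA59 0.31 ± 0.84 (edgeR adjusted p = 0.102, 0.977, 0.611 and 0.831). The plastid-encoded median was 0.19 (camera adjusted p = 0.0302, adjusted p = 0.721 with an estimated correlation). Among called differences, those of AT1G73325, ERF1, GRXC9, JOX4, LTP3, LTP4 and WRKY40 moved by more than 1.5 times in at least 1 alternative.

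Medians of JA-responsive genes differed by history under challenge in the direction of their response, with camera support that did not hold over all readings. JA-induced genes chosen in replicates 1 and 2 (547) had a median history effect under challenge of 0.36 in replicates 3 and 4, 72.4% of them positive (camera p = 6.74e-11, p = 0.0202 with an estimated correlation), and those chosen in replicates 3 and 4 (609) had 0.18 in replicates 1 and 2, 59.6% positive (camera p = 0.00677, p = 0.414 with an estimated correlation). JA-lowered genes (333 and 582) had -0.71 and -0.81 (camera p = 4.95e-16 and 4.11e-09; p = 0.0356 and 0.134 with an estimated correlation). With an estimated correlation 1 of 6 readings passed 0.05 for each list over all pairings of replicates: the other pairings gave p = 0.142 to 0.316 for induced and 0.0561 to 0.102 for lowered genes. Averages over the 2 readings were 0.27 for induced and -0.76 for lowered genes. Without challenge the induced genes already had 0.66 and 0.62 (average 0.64), and the lowered genes -1.63 and -1.53, a reading added after the data were seen.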

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

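The tests of exchanged libraries and of the ratio over genes lower in JA-history plants, alone and in every pairing of replicates, were chosen after seeing the results; the other tests here were fixed earlier. Chance in the grouping of libraries was tested by dividing the 8 libraries of a comparison in all 35 ways. Only 1 division, the real one, called as many genes for each pairwise comparison: 5147 against at most 264 in any other for the challenge of water-history plants, 6138 against 33 for that of JA-history plants, and 7710 against 520 for history under challenge. For history without challenge the real division called 12471 and the highest other 2765, from exchanging W_W replicate 4 with JA_W replicate 1. The real division thus ranked first of 35 for each of these 4. That is the most extreme rank that 35 divisions allow, so it argues against chance only to 1 in 35 and does not exclude it. For the interaction, 100 divisions were used, the real one and others drawn at random, with histories exchanged within each challenge level. Of these, 2 called as many as the real 3539, the real one included. The other, with 8139, kept the true histories of unchallenged libraries and mixed those of challenged ones, so it read the history effect itself. Such exchanges also break the history effect, so this rank cannot decide whether the interaction arose by chance.

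The challenge response differed between histories for 1539 genes in the positive and 2000 in the negative direction. It differed for 12 lists by median: JA catabolism (1.27), MYC-branch outputs (-0.67), SA pathway (1.43), ethylene pathway (0.39), aliphatic glucosinolates (-0.76), indole glucosinolates (0.48), tryptophan synthesis (1.09), anthocyanin and flavonoid (-1.67), senescence (0.43), ABA response (-0.56), touch and early wound (0.79) and plastid-encoded (0.19). All 12 camera calls were lost with an estimated correlation, where the lowest adjusted p was 0.419. Of 54 genes looked at, 18 differed. Log2 differences were -2.28 for VSP1, -3.65 for VSP2, -3.33 for LBD1, -2.66 for WSD1, -4.76 for LTP3, -6.22 for LTP4, -5.14 for AT1G73325, -4.47 for CSLA01, -2.95 for CHS and -2.65 for NUDT24. They were 2.84 for RAP2.6, 4.82 for LAS1, 4.53 for NIMIN1, 4.07 for GRXS13, 4.05 for GRXC9, 3.96 for AT3G22620, 3.81 for AT5G22545 (3 reads in JA_W) and -3.68 for AT1G72140 (1 read in W_W). The edgeR calls of RAP2.6, LTP3, LTP4, AT3G22620 and AT1G72140 were lost in at least 1 alternative.

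SA pathway genes were lower in JA-history plants without challenge, with a median of -4.09. No single library carried this: at least 23 of 23 members were called lower in edgeR whichever library was left out. Scaling did not carry it, since the highest median under another scaling was -4.01. Nor did an exchange of single libraries between histories. The lowest water-history library (5.32 mean log2 CPM) lay 1.78 above the highest JA-history library (3.54). An exchange of all labels of a group would separate the libraries as cleanly, so this comparison cannot detect it. A difference in infection or growth place that followed history was confounded with the spray, could not be tested and remained open. Whether the seedling spray itself lowered SA transcripts for 3 weeks therefore stayed a hypothesis.

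The history difference was smaller under challenge than without it, by ratios of 1.57 to 2.15 for genes chosen by their effect without challenge. Chosen instead under challenge in the other 2 replicates, genes higher in JA-history plants had a lowest ratio of 1.05 (SD between readings 0.14). It lay above 1 but by less than 1 SD, so for these the choice of genes cannot be told apart from narrowing. Genes lower in JA-history plants had 1.52 and 1.28 (SD 0.17). Over every pairing of replicates their ratios ran from 1.13 to 1.65 (SD 0.22), and 1.13 lay within 1 SD of 1, so narrowing stayed open for these too. No ratio in either direction was below 1, so both verdicts rest on that margin of 1 SD. The SD came from few readings, or from pairings that share libraries, and is itself uncertain.

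Single libraries stood apart in 24 of 336 sets of 4 replicates, where chance alone would give 16.8. The figure beside each is the gap to the nearest replicate over the range. The share of the 10 most abundant genes was high in W_W replicate 4 (0.904; 8.48% against 6.91% to 7.06%) and low in JA_W replicate 1 (0.835; 7.92% against 8.96% to 9.16%), and the plastid share was high in W_JA replicate 1 (0.892). List means stood apart for aliphatic glucosinolates in W_W replicate 1 (0.868), photosynthesis in JA_W replicate 1 (0.851) and ABA response in W_W replicate 3 (0.930). JA_JA replicate 1 was low for VSP1 (0.886), VSP2 (0.830) and CYP81F4 (0.911), and JA_JA replicate 2 for JAZ10 (0.969) and RAP2.6 (0.832). GLIP1 was low in W_JA replicate 3 (0.841), LBD1 high in W_W replicate 1 (0.894), AT4G02850 low in W_JA replicate 4 (0.830) and AT3G22620 low in JA_W replicate 4 (0.945). A ratio of 1 arose where only 1 replicate had reads: AT5G26260, AT1G14120 and AT1G72140 in W_W, 5MAT in W_W, GLIP1, ARD3 and AT2G44240 in JA_JA, and AT4G05540 in JA_W and JA_JA.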

How the results depend on the processing

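The tests with library totals only, without 2 libraries that stood apart, and of the lists read without challenge were chosen after seeing the results. With library totals only, the challenge of water-history plants raised 1683 genes and lowered 3763, in place of 2674 and 2473; the cause was not tested. A fold over 2 left 707 and 759 genes there, 936 and 556 for the challenge of JA-history plants, 1566 and 2573 for history without challenge, 542 and 1435 for history under challenge, and 529 and 343 for the interaction, fewer by construction. A threshold of 0.01 left 1691 and 1393 for the challenge of water-history plants, 1929 and 1866 for that of JA-history plants, 1870 and 2742 for history under challenge, and 602 and 795 for the interaction.

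Interaction counts moved from 1539 and 2000 to between 1012 and 2015 more positive and between 1332 and 2480 more negative when 1 library was left out. Without both JA_W replicate 1 and W_W replicate 4, 2450 were more positive. These 2 lay nearest the other history on the first component among unchallenged libraries; the cause was not tested. With the estimated correlation camera called 6 of 24 lists for the challenge of water-history plants and 4 for that of JA-history plants. It called 0 for history without challenge, 0 under challenge and 0 for the interaction, where 2, 3 and 0 lists had an unadjusted p under 0.05 and fry called 17, 12 and 10.

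With the replicate number as a replicate block, PR1 in the challenge of water-history plants had a log2 change of -0.18 in place of 0.08. Replicate numbers did not pair across groups: 5 of 24 pairs with the same number correlated above 0.1, with a median of -0.022. PR1 had -0.0298 with library totals only, -0.16 without both libraries, and -0.32 to 0.42 when 1 was left out. The interaction of JAZ10, -0.03, became 0.0227 with DESeq2, 0.0137 with RLE scaling, 0.49 without both libraries, and -0.36 to 0.33 when 1 was left out. Leaving 1 out gave -0.0808 to 1.09 for PDF1.2a, -0.41 to 0.85 for ORA59 and -0.0444 to 3.49 for PR1. None of these 5 results was called by edgeR, and the cause was not tested.

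With other pairs of replicates, JA-lowered genes had a history effect under challenge of -0.87 and -0.92 in place of -0.76, averages of 2 readings each; single readings ran from -1.42 to -0.32. JA-induced genes had one without challenge of 0.56 and 0.59 in place of 0.64, with single readings from 0.30 to 0.82. Over genes called in either history the challenge responses correlated at 0.74 in place of 0.69. Of 411 results called by edgeR for named genes, 362 kept their call in every alternative run per gene (at most 26) and 49 lost it in at least 1. Most of these genes were named for large changes in the same data, which favours keeping a call. Over all called genes the lowest share kept in an alternative was 66.1%, for the interaction without JA_W replicate 2. A fold over 2 and the threshold of 0.01 were not run per gene. The fold moved by more than 1.5 times in at least 1 alternative for 62 of the 411. Of 16 uncalled ones, 4 gained a call and 5 changed sign. With 4 replicates and about 32190200 to 34319900 reads, interaction changes of 1.5-fold were called in 12% of simulated genes, so a missing call is weak evidence of no change.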

Other observations

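The gene family and length-weighted tests were chosen after seeing the results, as were the families named. A family was a gene description shared by at least 10 tested genes. Descriptions with hypothetical, unknown or uncharacterized, or ending in transmembrane protein, were left out. The remaining 174 families were compared with all genes in 1740 Fisher tests, of which 60 passed the threshold. Members of a family are not independent. Pentatricopeptide repeat genes, which process organelle RNA, were higher in unchallenged JA-history plants for 130 of 177 (73.4% against 33.8% of all genes, median log2 0.62, Fisher adjusted p = 5.41e-24). Tetratricopeptide repeat genes were so for 165 of 254 (65.0%), mitochondrial transcription termination factors for 25 of 30 (83.3%) and TCP-1/cpn60 chaperonins for 12 of 12. TIR-NBS-LRR disease resistance genes were lower for 42 of 47 without challenge (89.4% against 31.1%, median -1.06) and 39 under it (83.0% against 21.2%, median -0.71). CC-NBS-LRR genes were lower for 13 of 19 without challenge (68.4% against 31.1%) and for 13 under it (68.4% against 21.2%). EF-hand calcium-binding genes were lower for 21 of 30 without challenge (70.0%, median -1.33) and 17 under it (56.7%, median -0.41). Pathogenesis-related thaumatin genes were higher for 9 of 11 without challenge (81.8%, median 0.94), and leucine-rich repeat protein kinases for 29 of 85 under it (34.1% against 18.9%). Challenge raised 17 of 41 MATE efflux genes in water-history plants (41.5% against 13.9%) and 17 in JA-history plants (41.5% against 15.4%). It lowered 13 of 18 DEAD-box RNA helicase genes in JA-history plants (72.2% against 16.5%).

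MYC2 was listed with 0 reads in all 16 libraries. Of its exonic bases 98.5% lie under the opposite-strand gene AT1G32630, which had 1499 reads over the 16. Genes covered in this way for 95% or more were at 0 for 392 of 453 (86.5%), against 15.4% without overlap, a ratio of 5.63 that fits reads over shared exons being left out of the counts. Weighted to the same exon lengths the share without overlap was 37.2% and the ratio 2.33, so for these genes as a set short models cannot be told apart as part of the cause. MYC2 itself has 3289 exonic bases, against a median of 1523 for genes without overlap. The 0 may therefore be a matter of counting, and no statement on MYC2 expression was made.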
